A study of Mus musculus with 7 samples.

How the data were processed

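Gene expression was measured by RNA sequencing in naive CD4 T cells, the helper T cells that have not yet met their antigen, from the spleen of 7 male C57BL/6 mice aged 8 weeks. Of these mice 3 were wild type (WT) and 4 carried a gain-of-function (GOF) allele of Pik3cd, which encodes the p110delta catalytic subunit of phosphoinositide 3-kinase. Per the labels' protocols, controls were littermates, the cells were isolated without culture by negative selection with a commercial kit, and paired-end libraries were made from total RNA with the Illumina TruSeq RNA kit. Groups and replicate numbers were taken from the sample titles, and columns were matched to samples through the sample descriptions. Each library is one mouse, so the spread within a group includes that between animals.

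The authors deposited 1 table with a raw count and an FPKM per gene and library for 34745 genes, with Ensembl identifiers, symbols and loci. Per the submitters' processing notes, the tools named are HISAT2 2.0.4, Cufflinks 2.1.1 and Cuffdiff, and the genome build is mm10. Their roles, the counting rule, the treatment of multiply mapped reads and the strand setting are not given in the sources used here. The deposited FPKM is the deposited count divided by a length fixed per gene and by the column total of counts, which held within 0.1% for 100% of values, so the FPKM columns add no between-library scaling beyond the totals. Coordinates are printed as deposited, on mm10, and 80.8% of loci were identical to those of GENCODE M21, which was used for gene type, GC content and transcript length. In the symbol column 27 symbols had been turned into dates and 67 symbols occurred more than once, so rows were followed by Ensembl identifier. Members of gene lists and named genes were matched by symbol. Counts of 16172 genes were 0 in all libraries. Processed pseudogenes carried many counts in places, so values of genes with near-identical copies (ribosomal protein, globin, immunoglobulin, Gbp and Apol9 genes among them) are uncertain, as are those of overlapping and antisense genes.

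The counts were tested with the edgeR quasi-likelihood method (edgeR 4.0.16 in R 4.3.3, limma 3.58.1) with filterByExpr, TMM normalization, default settings and all 7 libraries in one 2-group model, and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. The plan had assumed FPKM and limma and named edgeR for the case that raw counts were present, which was the case. Of the deposited genes 12668 passed the filter. Values are CPM (counts per 1000000 counts) computed from the deposited counts with TMM-scaled totals, as mean ± SD over 3 WT and 4 GOF libraries. The standard error (SE) of a log2 fold change, always GOF against WT, was obtained from the fold change and the quasi-likelihood F statistic. Where all libraries of a group had 0 counts, the fold is a lower bound computed with 3 counts per library. Where a group had 1 to 3 counts in all, the ratio has an exact 95% counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

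Named genes follow a rule set before the data were examined. They are Pik3cd, the 10 largest rises and the 10 largest falls among genes past the threshold with non-overlapping groups and a mean FPKM of at least 2 in the higher group (predicted genes, pseudogenes and antigen receptor segments left out), and, in each gene list, up to 4 members past the threshold with the smallest p. Genes named outside this rule are said to have been chosen after their values were seen. The lists, also fixed in advance, were glycolysis, mTORC1 and MYC driven biosynthesis, FOXO1 targets high in naive cells, activation and memory markers, follicular helper, Th1 and cytotoxic, Th2, Th17, regulatory T cell, immediate early, cell cycle, interferon response, oxidative phosphorylation, sterol and fatty acid synthesis, PI3K pathway, T cell receptor signalling, apoptosis, ribosomal proteins, markers of B cells, plasma cells, myeloid cells, neutrophils, NK and CD8 T cells, red blood cells and platelets, and stroma, plus sex-linked genes as a check of the samples. The first 25 were tested with camera (2-sided, preset correlation 0.01), which compares a list with all other genes, with Benjamini-Hochberg adjustment over the 25. The test with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were run beside it. A library's list score is the mean log2(CPM + 0.5) of the members. Measures of a whole library were compared with exact 2-sided permutation tests, which with 3 against 4 libraries cannot give a p below 0.0571. No measured library pair agreed within sampling noise, so all 7 libraries count.

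Counts were simulated for these 12668 genes with the group sizes and depths of this comparison and noise drawn from the fitted dispersion trend. Of 100 genes changed by 1 on the log2 scale edgeR recovered 70%, and of 100 changed by 2 it recovered 94%, with 8 false calls among 172. Far more genes were called in the real data, so these rates hold for the simulated setting only. Total counts ranged from 14497957 to 16293539 per library, which puts 3 counts at 0.184 to 0.207 CPM. The biological coefficient of variation was 20.2%. Alternatives set in advance were limma on log2(FPKM + 1), with pseudocounts of 0.1 and 0.5, on TPM, after quantile normalization, without trend and robust fitting and with array weights, DESeq2 1.42.0, no low count filter, a mean FPKM of at least 5, median of ratios scaling, the replicate number as a block, and each library left out in turn. Alternatives added after the data were seen were the removal of GC and length trends, GOF replicates 1 and 3 or 2 and 4 left out, a marker score as covariate and robust edgeR dispersions. The plots were drawn with matplotlib in Python.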

Results

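Naive CD4 T cells from the spleen of 3 wild-type (WT) mice and of 4 mice with a gain-of-function (GOF) allele of Pik3cd were profiled by RNA sequencing, to find the genes expressed differently in the mutant cells. The WT libraries held 14497957, 15015783 and 14643134 counts and the GOF libraries 14945520, 15296355, 16293539 and 15293096. A count above 0 was found for 14096, 15264 and 14042 genes in the WT libraries and for 16030, 15670, 15980 and 15350 genes in the GOF libraries. Mitochondrially encoded genes took 4.78% ± 0.409 (SD, n = 3) of counts in WT and 6.36% ± 0.432 (SD, n = 4) in GOF, with no overlap between the groups (exact permutation test, 2-sided, p = 0.0571, the smallest this design allows). The first principal component held 67.0% of the variance and separated the genotypes. It also set GOF replicates 1 and 3 (57.12 and 57.45) apart from GOF replicates 2 and 4 (37.9 and 40.02). The WT libraries lay between -71.71 and -53.83. None of the 4 tested Y-linked genes differed between the groups (edgeR, adjusted p = 0.2005 for Uty and 0.458 for Ddx3y, the 2 with the smallest p). Their log2 fold changes were -0.36 and -0.24, and both groups were labelled male.

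Pik3cd itself (ENSMUSG00000039936, mm10 chromosome 4, 149649168 to 149702571, a protein-coding gene) was expressed at 938, 1511 and 959 CPM in the WT libraries and at 543, 762, 538 and 765 CPM in the GOF libraries. Its mRNA fell from 1136 ± 325 CPM (SD, n = 3) in WT to 652 ± 129 CPM (SD, n = 4) in GOF, a log2 fold change of -0.80 with an SE of 0.20 (edgeR quasi-likelihood, adjusted p = 0.0154). All 4 GOF libraries lay below all 3 WT libraries. The counts are per gene and do not show the allele. Without GOF replicates 1 and 3, left out after the data were seen because markers of other cells were highest in them, the log2 fold change was -0.58 (adjusted p = 0.106), and without replicates 2 and 4 it was -1.06 (adjusted p = 0.0173). With a marker score as covariate, also added after the data were seen, it was 0.22 (adjusted p = 0.850), and over the alternatives the adjusted p ran from 0.000487 to 0.850.

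Among 12668 tested genes, 2130 were higher and 1838 lower in GOF cells, of which 1215 rose and 515 fell at least 2-fold. The balance of the directions depended on the scale, with 2088 higher and 1255 lower in limma on log2(FPKM + 1) and 1574 higher and 1712 lower after quantile normalization in limma. The groups did not overlap for 2069 of the higher and 1756 of the lower genes, and for 5037 of all tested genes, where chance gives 5.71%. Camp, an antimicrobial peptide of neutrophil granules (mm10 chromosome 9, 109847379 to 109849617), Car1, a carbonic anhydrase of red blood cells, Apol9b, an apolipoprotein L family gene, and Il18, an inflammatory cytokine, had 0 counts in the WT libraries. Their GOF means of 5.11 ± 3.66, 4.92 ± 2.89, 4.84 ± 0.657 and 2.08 ± 1.35 CPM (SD, n = 4) put them at least 24.3-fold, 23.4-fold, 23.0-fold and 9.90-fold higher. Itgad, an integrin alpha chain, rose from 3 counts over the WT libraries together to 914 over the GOF libraries together, a ratio of 209 with a counting interval of 70.4 to 1002. Penk, which encodes the opioid precursor proenkephalin, rose 111-fold (counting interval 38.8 to 555) to 7.99 ± 0.439 CPM. Fcgr4, an Fc receptor of myeloid cells, rose 131-fold from 1 count (24.03 to 5377). Slc40a1, the iron exporter ferroportin, rose 132-fold to 27.7 ± 19.6 CPM, and after quantile normalization in limma its log2 fold change was 1.23 and its call was lost (adjusted p = 0.0504). Cd5l, a secreted macrophage protein, rose 99.97-fold to 14.1 ± 9.87 CPM (SD, n = 4). Ngp, a neutrophil granule protein, rose to 30.4 ± 21.2 CPM, and its 13 WT counts were all in WT replicate 1, so that its fold rests on that library. The 3 WT counts of Itgad were all in WT replicate 2 and the 3 of Penk all in replicate 1. For 8 of these 10 genes, all but Apol9b and Penk, GOF replicates 1 and 3 lay above 2 and 4, as for the myeloid markers. Adjusted p-values of these 10 genes lay between 7.32e-05 for Penk and 0.00445 for Il18 (edgeR).

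Among the largest falls, Ecm1, a secreted matrix protein (ENSMUSG00000028108, mm10 chromosome 3, 95734147 to 95739569), fell from 2837 ± 755 CPM (SD, n = 3) to 71.8 ± 6.39 CPM (SD, n = 4), a 39.5-fold lower level (log2 fold change -5.30, SE 0.19, edgeR adjusted p = 5.90e-07). Slc30a4, a zinc transporter (mm10 chromosome 2, 122681233 to 122702663), fell from 310 ± 31.7 to 16.9 ± 0.648 CPM (log2 fold change -4.20, SE 0.10, edgeR adjusted p = 6.54e-08). Gpr34, a receptor for lysophosphatidylserine, fell from 118 to 4.93 CPM, Myo6, an unconventional myosin, from 102 to 3.27 CPM, and Map6, a microtubule-stabilising protein, from 76.1 to 1.23 CPM. Ccl22, a chemokine that binds CCR4, fell from 47.4 ± 30.2 to 1.32 ± 0.765 CPM. Gucy1a3, a subunit of soluble guanylate cyclase, fell 22.1-fold, Pgpep1l 22.6-fold and Prss12, a serine protease, 80.1-fold. Akr1c18, the 20-alpha-hydroxysteroid dehydrogenase, was at 4.61 ± 0.611 CPM in WT and had 0 counts in the GOF libraries, at least 24.3-fold lower. These genes had edgeR adjusted p-values of at most 0.000249. At a mean FPKM of at least 5, which leaves 6502 genes, 1093 were higher and 1069 lower. Without GOF replicates 1 and 3 the counts were 1074 and 1050, and without GOF replicates 2 and 4 they were 1764 and 1358. With the marker score as covariate, which itself differs between the genotypes, 126 were higher and 91 lower. That covariate ended the call of 68 named gene values and turned the direction of 6, Pik3cd and 5 others.

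**Figure D1:**
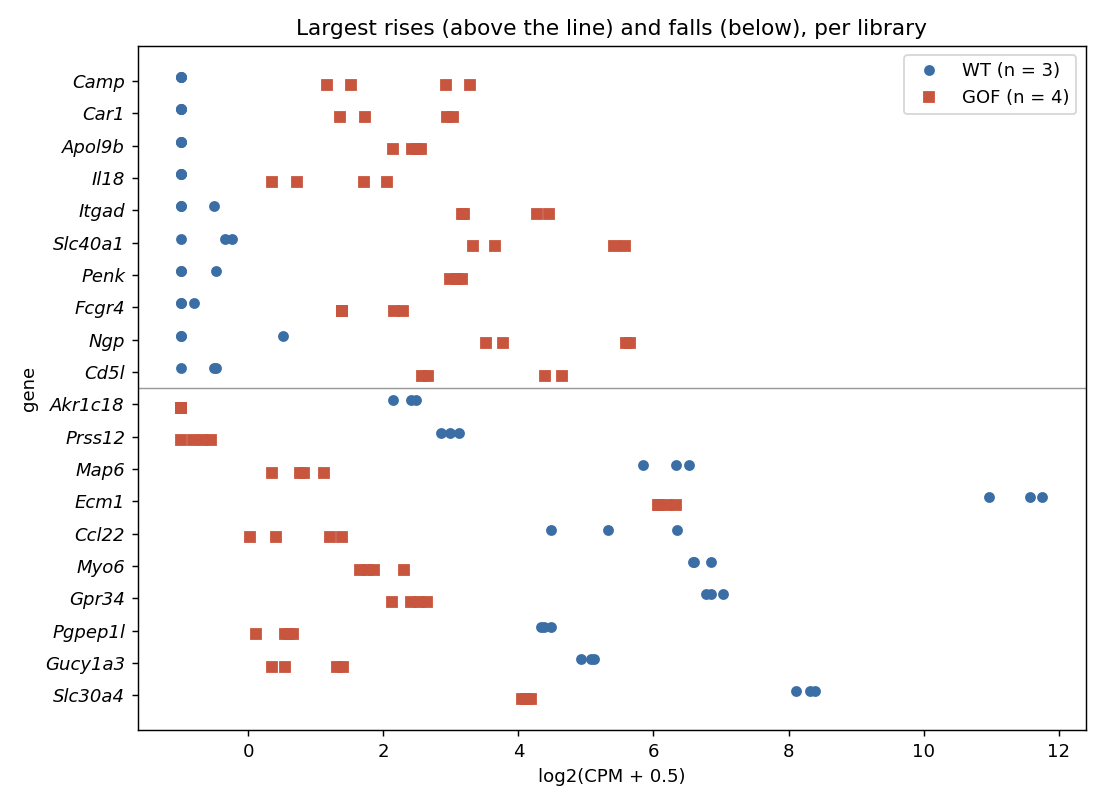
Log2(CPM + 0.5) of the 10 genes with the largest rises and the 10 with the largest falls, 1 point per library, circles for the 3 WT and squares for the 4 GOF libraries, so that 0 counts lie at -1. The groups do not overlap for any of the 20 genes, and for 8 of the 10 rises, all but Apol9b and Penk, GOF replicates 1 and 3 lie above 2 and 4.

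Markers of cells other than CD4 T cells were higher in GOF libraries, although the cells had been isolated by negative selection. Of 19 myeloid markers tested 15 rose and 0 fell (15 and 0 adjusted over the list alone), with a median log2 fold change of 2.05 (camera adjusted p = 2.67e-07; adjusted p = 0.348 with an estimated correlation). C1qa, a complement component made by macrophages, rose from 0.325 ± 0.258 to 30.1 ± 19.5 CPM. Vcam1, an adhesion molecule of macrophages and stroma, rose from 0.681 to 50.2 CPM, Csf1r, the receptor for M-CSF, from 2.80 to 42.8 CPM, and Cebpb, a transcription factor of myeloid cells, from 5.71 to 20.4 CPM. Neutrophil markers rose in 9 of 10 cases (10 adjusted over the list alone), with a median of 5.03, or 4.75 with Camp at its bound, and 8.85 without WT replicate 1 (camera adjusted p = 5.29e-06; adjusted p = 0.267 with an estimated correlation). Among them Csf3r, the G-CSF receptor, reached 13.02 ± 2.84 CPM and Cxcr2, a chemokine receptor, 2.58 ± 0.213 CPM in GOF. For the median of 8.85 the WT side was replicates 2 and 3, with neutrophil scores of -0.74 and -0.86. These lie near the level of 0 counts, so the size of that median is uncertain. For B cells 13 of 18 markers rose and 0 fell (16 and 0 adjusted over the list alone; median 1.51; camera adjusted p = 5.15e-05; adjusted p = 0.469 with an estimated correlation). Ighm went from 334 ± 21.2 to 784 ± 178 CPM, Igkc from 34.1 ± 19.0 to 187 ± 89.7 CPM, Cr2 from 0.437 to 7.87 CPM and Ebf1 from 0.841 to 3.64 CPM.

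Of the markers of NK and CD8 T cells 11 of 13 rose and 0 fell (11 and 1 adjusted over the list alone; median 1.98; camera adjusted p = 8.36e-07; adjusted p = 0.267 with an estimated correlation). Of this list Eomes, Gzma, Nkg7 and Prf1 are also Th1 and cytotoxic genes. Cd8a and Cd8b1, chosen after their values were seen, had log2 fold changes of -0.78 and -0.23 and did not pass the threshold (edgeR adjusted p = 0.0972 and 0.300). Plasma cell markers did not pass as a list (2 of 6 higher and 1 lower, the same adjusted over the list alone; camera adjusted p = 0.285). Jchain, the joining chain of polymeric antibodies, rose from 3.38 to 37.3 CPM, while Prdm1 fell and Irf4 rose. The call of Irf4 was lost without GOF replicates 1 and 3 and without 2 and 4 (edgeR adjusted p = 0.0608 and 0.0645). Without WT replicate 2 that list passed (adjusted p = 0.0254). Red blood cell and platelet genes did not pass either (5 of 10 higher and 0 lower, 7 and 1 adjusted over the list alone; median 1.95, or 1.94 with genes at 0 at their bound; camera adjusted p = 0.0601). Their highest-ranked members were Gp9, at least 5.64-fold higher from 0 counts, and Hba-a2, Hbb-bt and Ppbp at GOF levels of 6.10, 6.70 and 3.02 CPM. The calls of Hba-a2 and Hbb-bt were lost without WT replicate 1 or 3 or GOF replicate 1 or 3 (adjusted p = 0.0511 to 0.0718 and 0.0634 to 0.0970). Hbb-bt also lost its call in limma on log2(FPKM + 1), with a pseudocount of 0.5, on TPM, after quantile normalization and without trend and robust fitting (adjusted p = 0.0504 to 0.0815). The call of Ppbp was lost without any single library but GOF replicate 2 (0.0525 to 0.116). The list passed without any of the WT replicates or without GOF replicate 2 or 4 (adjusted p = 0.0141 to 0.0419), and without GOF replicates 2 and 4 together (median 3.25, adjusted p = 6.19e-07). For stroma 1 of 7 genes, Pecam1, fell from 382 to 227 CPM, 0 rose, the same adjusted over the list alone, and the list did not pass (median -0.03; camera adjusted p = 0.583). With the marker score as covariate the stroma list passed downward (median -1.58, adjusted p = 0.00176), as did the red blood cell and platelet list (median -1.43, adjusted p = 0.0307). The myeloid score was 4.30 and 4.35 in GOF replicates 1 and 3 and 3.18 and 3.31 in replicates 2 and 4, against 1.24 to 1.68 in WT.

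**Figure D2:**
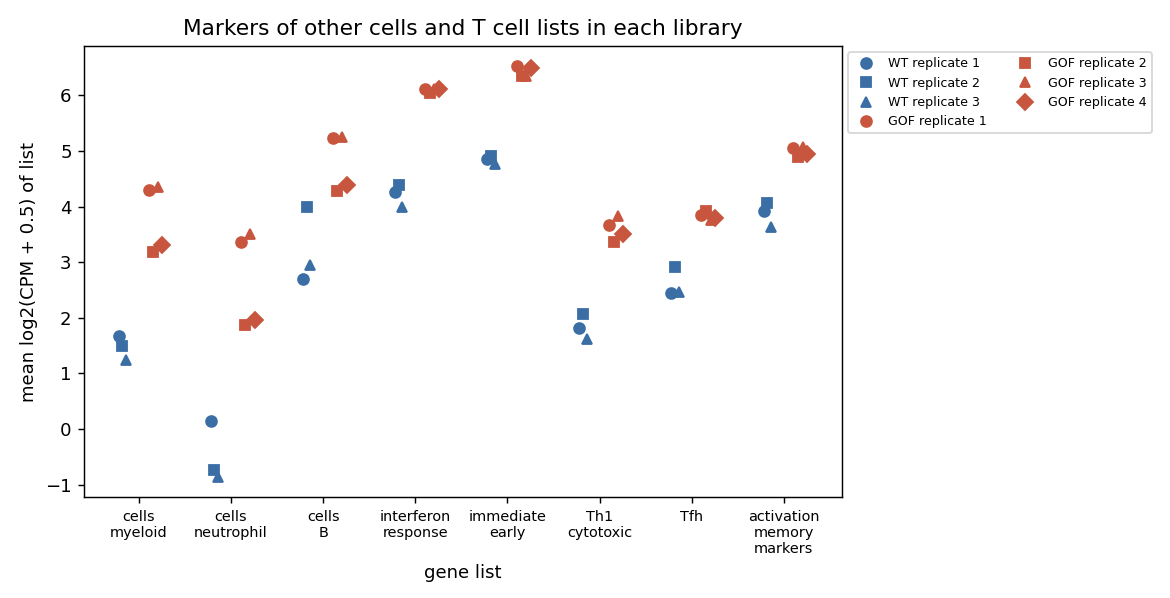
Mean log2(CPM + 0.5) over the members of 8 gene lists in each library, WT in blue and GOF in red with 1 symbol per replicate. Myeloid, neutrophil and B cell markers are higher in GOF replicates 1 and 3 than in 2 and 4, whereas the interferon response score lies between 6.05 and 6.12 in all 4 GOF libraries and between 3.99 and 4.38 in WT.

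Genes induced by interferon rose together. Of 26 tested, 23 rose and 1 fell, the same adjusted over the list alone, and the median log2 fold change was 2.25 (camera adjusted p = 1.63e-29; adjusted p = 0.0390 with an estimated correlation). Mx1, an antiviral GTPase, rose from 0.420 ± 0.0615 CPM (SD, n = 3) to 12.7 ± 0.917 CPM (SD, n = 4), a log2 fold change of 4.89 with an SE of 0.23 (edgeR adjusted p = 2.52e-06). Ifit3, an interferon-induced RNA-binding family member, rose 7.38-fold to 46.3 CPM. Rtp4 rose 6.25-fold to 67.1 CPM and Irf7, the transcription factor that amplifies type I interferon production, 3.40-fold to 109 CPM. Ifi47, an interferon-induced GTPase and the 1 member that fell, had a log2 fold change of -0.30 (edgeR adjusted p = 0.0259; chosen after its value was seen). The score of this list varied by an SD of 0.0341 among the 4 GOF libraries, against 0.625 for the myeloid markers, whose median log2 fold change was 2.05 in the same libraries.

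Immediate early genes, which are transcribed within minutes of receptor stimulation, were also higher. Of 25 tested, 17 rose and 2 fell (18 and 2 adjusted over the list alone), with a median log2 fold change of 1.55 (camera adjusted p = 1.64e-09; adjusted p = 0.0390 with an estimated correlation). Egr1 rose from 20.2 ± 3.20 to 99.8 ± 4.52 CPM (log2 fold change 2.30, SE 0.13, edgeR adjusted p = 5.95e-06). Junb, an AP-1 subunit, rose from 372 to 1886 CPM, Nfkbid, an atypical inhibitor of NF-kappaB, from 22.02 to 145 CPM and Dusp5, a phosphatase of ERK, from 44.2 to 124 CPM. Nr4a1, an orphan nuclear receptor induced by antigen receptor signals, rose from 5.59 to 247 CPM, and Nfkbia and Ier5 fell (log2 fold changes -0.89 and -0.36, edgeR adjusted p = 0.00329 and 0.0146), all 3 chosen after their values were seen. Of the genes of T cell receptor signalling 12 of 28 rose and 3 fell, the same adjusted over the list alone, with a median of 0.25 (camera adjusted p = 0.00966; adjusted p = 0.353 with an estimated correlation). Cd5 and Cd6, surface receptors that dampen T cell receptor signals, rose from 251 ± 18.8 to 721 ± 39.1 CPM and from 287 ± 11.2 to 823 ± 34.1 CPM. Ptpn6, the phosphatase SHP-1, rose from 152 to 310 CPM, and Rasgrp1, an activator of Ras, fell from 1242 to 537 CPM. Myeloid markers rose in the same libraries, with a median log2 fold change of 2.05.

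Activation and memory markers went both ways, with 19 of 28 higher and 7 lower, the same adjusted over the list alone, and a median of 1.77 (camera adjusted p = 1.01e-05; adjusted p = 0.229 with an estimated correlation). Cd69, an early activation marker, rose from 44.9 ± 14.1 to 385 ± 25.8 CPM. Lgals1, galectin-1, rose from 14.7 to 105 CPM and Maf, a transcription factor of follicular helper and IL-10 producing T cells, from 4.93 to 49.1 CPM. Tnfsf8, the CD30 ligand, fell from 315 to 79.0 CPM. Cd44, whose protein marks memory cells, rose from 7.25 to 41.6 CPM, and Il2ra, the IL-2 receptor alpha chain, fell from 44.6 to 29.0 CPM, both chosen after their values were seen. Of the follicular helper genes 8 of 11 rose and 2 fell (8 and 3 adjusted over the list alone), with a median of 2.34 (camera adjusted p = 0.00116; adjusted p = 0.229 with an estimated correlation). Bcl6, their lineage factor, rose from 8.47 ± 2.43 to 43.0 ± 1.21 CPM and Pou2af1, a transcriptional coactivator, from 6.55 to 35.9 CPM, whereas Slamf6, a SLAM family receptor, fell from 491 to 206 CPM. At a mean FPKM of at least 5 the list median was 0.48 and the test pointed down (adjusted p = 0.842). With pseudocounts of 0.1 and 0.5 in limma it did not pass (adjusted p = 0.0682 and 0.0573). Myeloid, neutrophil, B cell and NK and CD8 markers rose in the same libraries as both lists, with medians of 2.05, 5.03, 1.51 and 1.98.

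Th1 and cytotoxic genes rose in 12 of 16 cases and 0 fell (14 and 0 adjusted over the list alone), with a median of 1.99 (camera adjusted p = 4.03e-10; adjusted p = 0.229 with an estimated correlation). Tbx21, the T-bet transcription factor, rose from 0.915 ± 0.368 to 9.70 ± 2.33 CPM, and Eomes, its relative, from 2.30 to 22.8 CPM. Gzma, granzyme A, rose from 0.960 to 18.3 CPM and Nkg7, a protein of cytotoxic granules, rose 4.03-fold from 5.95 CPM. The list of NK and CD8 markers, 4 of them also on this list, was higher in the same libraries (median 1.98, 11 of 13 higher), while Cd8a and Cd8b1 did not pass. Myeloid, neutrophil and B cell markers were higher in the libraries of this and the 3 lists that follow (medians 2.05, 5.03 and 1.51). Of the Th2 genes 4 of 6 rose and 1 fell (5 and 1 adjusted over the list alone; median 2.33; camera adjusted p = 0.0409; adjusted p = 0.256 with an estimated correlation). The chemokine receptor Ccr8 rose from 0.0928 to 8.16 ± 1.46 CPM (SD, n = 4), and 3 of its 4 WT counts were in WT replicate 2, without which its log2 fold change went from 6.33 to 7.55. Ccr4, also a chemokine receptor, rose 6.22-fold from under 1 CPM, and Gata3, the Th2 lineage factor, from 49.5 to 86.8 CPM. Il4ra, the IL-4 receptor alpha chain, fell from 1278 ± 112 to 441 ± 36.6 CPM. The Th2 call was lost in limma in all settings but log2(TPM + 1) (adjusted p = 0.123 to 0.192) and after removal of GC and length trends (adjusted p = 0.0533). Th17 genes did not pass (2 of 6 higher and 0 lower, the same adjusted over the list alone; camera adjusted p = 0.111), with Ccr6, a chemokine receptor, at 2.54 CPM in GOF. The Th17 list, with a median of 0.44, passed with fry (adjusted p = 0.0209) and without GOF replicates 2 and 4 (median 1.31, adjusted p = 0.0368). Without any of the WT replicates its median was 0.82 to 1.07. Regulatory T cell genes did not pass (9 of 16 higher and 5 lower, the same adjusted over the list alone; camera adjusted p = 0.0645). Foxp3, their lineage factor, rose from 30.6 ± 2.07 to 72.0 ± 3.58 CPM and Ikzf2, Helios, from 8.95 to 41.2 CPM. The TNF receptor family members Tnfrsf18 and Tnfrsf4 fell from 172 to 55.7 CPM and from 109 to 37.0 CPM. This list passed when WT replicate 1 or 2 or GOF replicate 2 or 3 was left out (adjusted p = 0.0390, 0.0333, 0.0487 and 0.0440), without GOF replicates 1 and 3 (0.0333), with no low count filter (0.0362) and with fry (0.0101). At a mean FPKM of at least 5 its median was -0.20 (adjusted p = 0.855).

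Cell cycle genes rose in 17 of 31 cases and fell in 2, the same adjusted over the list alone, with a median of 1.07 (camera adjusted p = 4.13e-05; adjusted p = 0.229 with an estimated correlation). Top2a, a topoisomerase of dividing cells, rose from 4.19 ± 1.16 to 34.4 ± 6.54 CPM, Mki67, the Ki-67 proliferation antigen, from 2.75 ± 1.46 to 27.1 ± 6.28 CPM and Cdk1 from 0.444 to 3.45 CPM. Bub1, a mitotic checkpoint kinase, had 0 counts in WT and 2.20 ± 0.451 CPM in GOF, at least 10.5-fold higher. Markers of myeloid cells, neutrophils and B cells were higher in the same libraries (medians 2.05, 5.03 and 1.51).

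FOXO1 targets high in naive T cells moved down as a list, with 13 of 22 lower and 5 higher (14 and 5 adjusted over the list alone) and a median log2 fold change of -0.45 (camera adjusted p = 0.00116; adjusted p = 0.348 with an estimated correlation). Bcl2, an inhibitor of apoptosis, fell from 1238 ± 70.8 to 181 ± 11.4 CPM (log2 fold change -2.77, SE 0.08, edgeR adjusted p = 3.83e-07), and S1pr1, the receptor for exit from lymphoid organs, from 909 ± 63.1 to 449 ± 31.9 CPM. Foxo1 itself rose from 252 ± 31.5 to 582 ± 50.8 CPM and Ddit4, an inhibitor of mTORC1, from 24.9 ± 9.61 to 158 ± 12.7 CPM. The list call was lost after quantile normalization (adjusted p = 0.0529), and without WT replicate 2 the median was -0.30. While the FOXO1 targets fell, markers of myeloid cells, neutrophils, B cells and NK and CD8 T cells were higher in the same libraries (medians 2.05, 5.03, 1.51 and 1.98). PI3K pathway genes did not pass, with 10 of 28 lower and 5 higher (11 and 5 adjusted over the list alone; median -0.22; camera adjusted p = 0.0840). Pik3r5, a regulatory subunit of PI3K gamma, fell from 471 to 223 CPM and Eif4ebp1, a translation repressor controlled by mTORC1, from 15.1 to 6.61 CPM. This list passed without WT replicate 1 (adjusted p = 0.0292), without GOF replicate 2 (0.0285), without GOF replicates 2 and 4 (0.0355) and with no low count filter (0.0306). Apoptosis genes went both ways, with 4 of 20 higher and 6 lower, the same adjusted over the list alone. Their median of 0.06 was positive while the mean of -0.06 and the test pointed down (camera adjusted p = 0.0601). Mcl1, an inhibitor of apoptosis, fell from 1824 to 841 CPM and Bcl2l11, the pro-apoptotic BIM, from 186 to 62.4 CPM, and Bak1, a pore-forming protein of apoptosis, rose from 45.1 to 83.5 CPM. That list passed downward without WT replicate 3 (adjusted p = 0.0343), at a mean FPKM of at least 5 (median -0.25, adjusted p = 0.00337), with no low count filter (0.0251), after removal of GC and length trends (0.0458) and with fry (0.00512).

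In mTORC1 and MYC driven biosynthesis 0 of 24 rose and 9 fell (10 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 0.00685; adjusted p = 0.469 with an estimated correlation). Myc fell from 222 ± 42.9 to 86.4 ± 10.1 CPM and Shmt2, a mitochondrial enzyme of 1-carbon metabolism, from 245 to 115 CPM. The nucleolar proteins Npm1 and Ncl fell from 1125 to 678 CPM and from 1086 to 746 CPM. In glycolysis 0 of 24 rose and 5 fell, the same adjusted over the list alone, with a median of -0.15 (camera adjusted p = 0.0197; adjusted p = 0.479 with an estimated correlation). Eno1, an enolase, fell from 474 ± 38.7 to 159 ± 10.3 CPM. The glycolytic enzymes Gpi1 and Pfkl fell from 647 to 360 CPM and from 102 to 56.9 CPM, and Hif1a, the hypoxia-inducible factor, from 250 to 112 CPM. The glycolysis call was lost without WT replicate 2 (median -0.04, adjusted p = 0.163), in limma in all settings but log2(TPM + 1) (adjusted p = 0.0573 to 0.215) and with fry (0.0573). Its median was -0.25 without WT replicate 1, -0.26 without WT replicate 3 and -0.08 without GOF replicate 2. Of 30 ribosomal protein genes 7 fell and 0 rose, the same adjusted over the list alone, with a median of -0.22 (camera adjusted p = 0.0328; adjusted p = 0.644 with an estimated correlation). Among them were Rps7, Rpl18 and Rpl6 at log2 fold changes of -0.68, -0.48 and -0.39. That call was lost without WT replicate 1, where the median was -0.11, GOF replicate 1 or GOF replicate 2 (adjusted p = 0.166, 0.0576 and 0.0907), without GOF replicates 2 and 4 (0.0669) and with fry (0.144). Rpl6 lost its call without WT replicate 1 (0.0629) or GOF replicate 1 (0.0547). In the libraries in which these 3 lists were lower, myeloid, neutrophil, B cell and NK and CD8 markers were higher, with medians of 2.05, 5.03, 1.51 and 1.98.

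Oxidative phosphorylation genes did not pass, with 3 of 31 higher and 0 lower (1 and 0 adjusted over the list alone; median 0.07; camera adjusted p = 0.383). Without WT replicate 2 the test of that list pointed down (median -0.000273, adjusted p = 0.921), and in 4 limma settings (log2(FPKM + 1), a pseudocount of 0.1, quantile normalization and array weights) the list passed upward (adjusted p = 0.0286 to 0.0498). Cox5b, Cox6c and Sdhb rose by 0.62, 0.49 and 0.39 on the log2 scale, and Cox5b kept its call without any single library. The call of Cox6c was lost without WT replicate 3 or GOF replicate 1, 3 or 4 (adjusted p = 0.0618 to 0.0827), and that of Sdhb without WT replicate 2 or 3 or GOF replicate 1, 3 or 4 (0.0712 to 0.0903). Sterol and fatty acid synthesis genes did not pass, with 4 of 24 higher and 5 lower, the same adjusted over the list alone. Their median of -0.05 and test pointed down while the mean was 0.03 (camera adjusted p = 0.541). Scd2, a stearoyl-CoA desaturase, rose from 20.3 to 119 CPM. Elovl6, a fatty acid elongase, fell from 66.9 to 20.8 CPM and Srebf2, a transcription factor of sterol synthesis, from 424 to 324 CPM. In all, 16 of 25 lists passed with the preset correlation, 2 with an estimated one (interferon response and immediate early) and 17 with fry. At a mean FPKM of at least 5 calls were lost for activation and memory (median 0.61, adjusted p = 0.0949), cell cycle (median 0.06, adjusted p = 0.842), neutrophil (0.0651), glycolysis (0.0651), mTORC1 and MYC (0.0503) and ribosomal protein lists (0.191). With the marker score as covariate they were lost for myeloid (median -0.03, adjusted p = 0.777), neutrophil (0.107), glycolysis (0.0644), mTORC1 and MYC (0.0575), Th2 (0.0669) and B cell lists (median -0.35, adjusted p = 0.857).

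**Figure D3:**
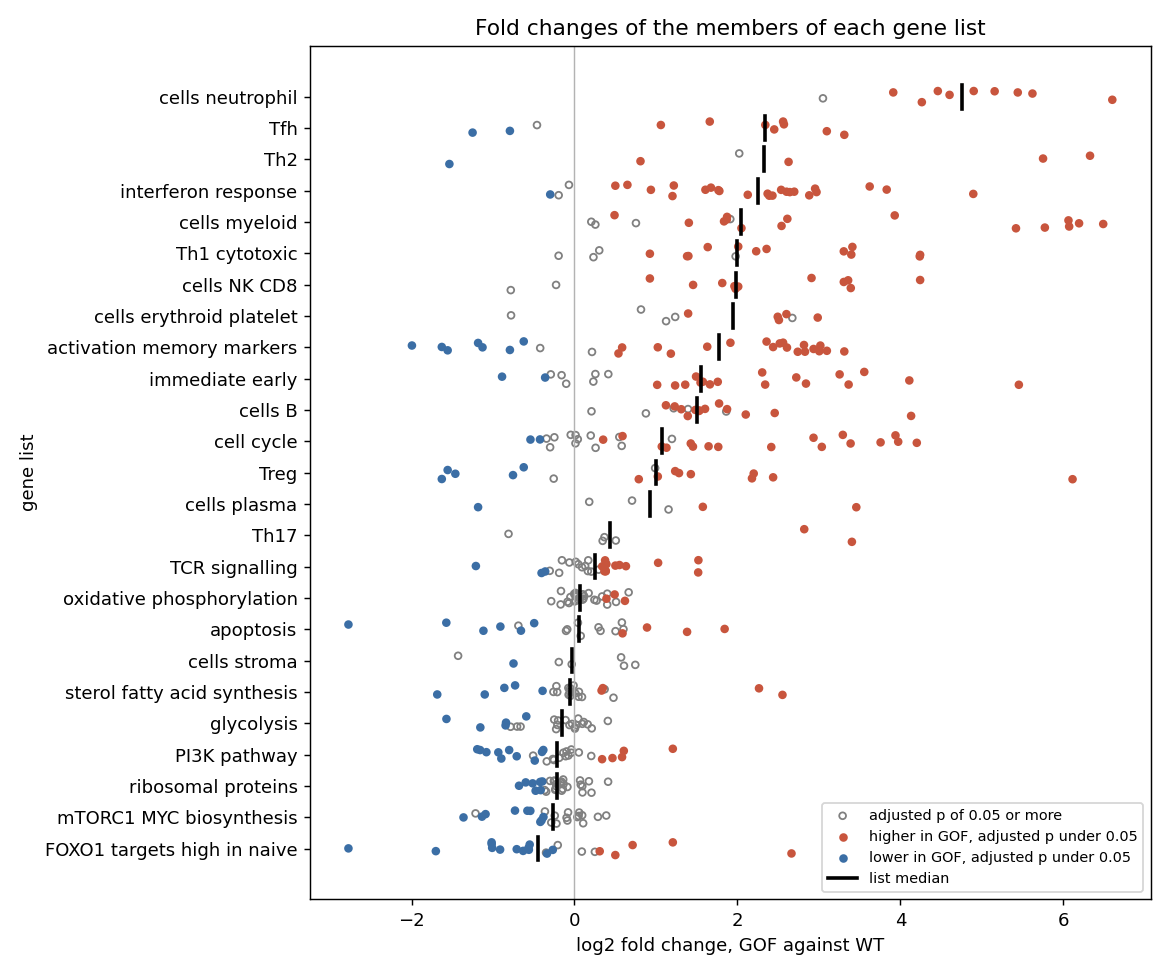
Log2 fold changes, GOF against WT, of the tested members of 25 gene lists, 1 point per gene, with red and blue for genes past the threshold upward and downward, open circles for the others and a black bar at the list median, over 3 WT and 4 GOF libraries. Genes with 0 counts in a group are drawn at their lower bound, and the median of the interferon response list lies at 2.25.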

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

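No explanation was tested for the results in this part, and the criterion was set before the data were examined. Of 136 sets of 4 GOF values (named genes, list scores and library measures), 5 had 1 library apart from the other 3, by a gap that took a larger share of the whole range than Dixon's test allows at the 95% level. Chance alone gives about 1 in 20. The share was 0.881 for Bcl2, where GOF replicate 2 had 198 CPM against 174 to 177 CPM in the others. It was 0.856 for Nkg7, with 18.1 CPM in GOF replicate 2 against 25.1 to 26.5 CPM. The interferon response score had a share of 0.883, with 6.05 in GOF replicate 2 against 6.11 to 6.12. The PI3K pathway score had 0.875, with 6.50 in GOF replicate 2 against 6.28 to 6.31. For sterol and fatty acid synthesis it was 0.879, with 5.39 in GOF replicate 4 against 5.47 to 5.48.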

How the results depend on the processing

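Settings chosen after the data were seen were the removal of GC and length trends, GOF replicates 1 and 3 or 2 and 4 left out, the marker covariate and robust dispersions. Over the settings, 2321 of the values of named genes other than Pik3cd kept their direction and side of the threshold, 117 lost significance and 5 reversed, and for lists 515 kept both, 48 lost significance, 36 gained it and 10 reversed. With each library left out in turn, 1615 to 2091 genes were higher and 1374 to 1819 lower, Pik3cd lay between -0.93 and -0.54 on the log2 scale, always past the threshold, and 15 to 18 lists passed. A mean FPKM of at least 5, which tests fewer genes (6502), gave 1093 higher, 1069 lower and 9 lists, and limma without trend and robust fitting gave 1225 lower. Leaving out GOF replicates 1 and 3 gave 1074 higher and 1050 lower, and Pik3cd at -0.58, while leaving out 2 and 4, with as many samples, gave 1764 and 1358, and Pik3cd at -1.06. With the marker covariate, which follows the genotype, 126 were higher and 91 lower, Pik3cd was at 0.22, and values reversed for Sdhb (-0.0123), Igkc (-0.37), Hba-a2 (-1.26), Hbb-bt (-3.15), Ppbp (-1.05) and the medians of B cell (-0.35), red blood cell and platelet (-1.43), plasma cell (-0.44), oxidative phosphorylation (-0.15) and PI3K lists (0.0105), of which the red blood cell and platelet list passed downward, as did stroma without a reversal (-1.58). The estimated correlation left 2 lists. Other reversals, for lists that did not pass under these settings, were stroma at 0.58 with no low count filter and 0.37 without GOF replicates 2 and 4, sterol synthesis at -0.00213 and follicular helper at 0.48 (by the test's direction) at a mean FPKM of at least 5, and oxidative phosphorylation at -0.000273 without WT replicate 2, the lowest of the values with 1 library left out, which reached 0.14. Beyond the fewer genes tested at the FPKM minimum, the cause was not tested. At that minimum the regulatory T cell median was -0.20, while the test kept its direction. DESeq2 called 2590 higher and 1995 lower, limma on log2(FPKM + 1) 2088 and 1255, and limma after quantile normalization 1574 and 1712, so that the majority turned. Medians of lists with low counts were smaller in limma on log2(FPKM + 1) (neutrophil 2.52, Th2 0.99, cell cycle 0.42). The median log2 fold change of all genes was 0.01, and 0.10 with no low count filter. Deviations of same-numbered libraries from their group means correlated at 0.326 for replicate 2 but at -0.0279 and -0.0365 for 1 and 3, whose WT libraries correlated best with another number, so the numbers were not taken as pairs. With the replicate block 1677 genes were higher and 1519 lower, Pik3cd was at -0.87 and 19 lists passed, among them PI3K (0.0393), apoptosis (0.0446) and red blood cell and platelet genes (0.0374), while Cox6c (0.0942), Hba-a2 (0.0564), Hbb-bt (0.0616) and Ppbp (0.0956) did not pass (adjusted p). Depth limits genes near 3 counts per library, 0.184 to 0.207 CPM.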

Other observations

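The tests that set excess ratios against marker lists, the test of STAT5-induced genes, the comparison of library totals and the removal of GC and length trends were chosen after the data were seen. The tests of genes near Pik3cd and of library splits are not in the plan fixed before the data were examined. Among the genes with the smallest p outside the named set, chosen after their values were seen, several at high expression fell in GOF cells. Tmem64 fell from 579 ± 27.5 to 87.8 ± 6.59 CPM, Sh3bp5, a binding partner of Bruton's tyrosine kinase, from 452 ± 27.3 to 75.3 ± 4.38 CPM, Wdr82, a subunit of histone H3K4 methyltransferase complexes, from 1079 ± 25.03 to 229 ± 16.4 CPM, and Pde2a, a cyclic nucleotide phosphodiesterase, from 386 to 72.3 CPM (edgeR adjusted p at most 2.00e-06). Trib2, a pseudokinase, fell from 895 to 341 CPM and Mtmr3, a lipid phosphatase acting on phosphoinositides, from 492 to 164 CPM. Adamtsl4, which lies near Ecm1 on chromosome 3 (mm10, 95676201 to 95687917), fell from 151 to 8.29 CPM. Dtx1, an E3 ligase tied to T cell anergy, rose from 27.1 ± 5.78 to 590 ± 20.9 CPM (SD, n = 3 and 4), a log2 fold change of 4.45 with an SE of 0.15 (edgeR adjusted p = 4.81e-07). Rgs2, a regulator of G protein signalling, rose from 24.4 to 141 CPM, Hsd11b1, which regenerates active glucocorticoid, from 13.6 to 120 CPM and Ampd1, an AMP deaminase, from 2.73 to 31.3 CPM. Gbp11 fell from 142 to 17.4 CPM while most interferon-induced genes rose, and reads shared with its close paralogs keep its level uncertain.

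Of 13 mitochondrially encoded protein genes tested, 7 were higher and 0 lower in GOF, with log2 fold changes from -0.12 to 0.71 and a median of 0.37, whereas 3 of 31 nuclear-encoded oxidative phosphorylation genes were higher. The difference between these 2 groups was not tested. In GOF replicates 1 and 3, where the myeloid score was highest, mitochondrially encoded genes took 6.71% and 6.67% of counts. In GOF replicates 2 and 4 they took 5.78% and 6.27%.

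The first pattern weighed is that lists of T cell state rose in GOF libraries together with markers of cells that negative selection should remove, such as Ighm at 784 CPM and C1qa at 30.1 CPM in GOF. The excess of the risen members over WT was compared between GOF replicates 1 and 3 and replicates 2 and 4. For myeloid markers it was 3.68 times as large in 1 and 3 (bootstrap interval 2.95 to 4.24). It was 1.05 times as large (0.987 to 1.13) for the interferon response and 0.915 times (0.865 to 1.06) for immediate early genes. Both intervals lay below the lowest interval end (1.21, NK and CD8) of the 5 marker lists with at least 5 risen members. The replicates were grouped because markers were highest in 1 and 3, so high ratios for marker lists were built in. Intervals resample genes and cover no spread between libraries. Over all 2130 genes higher in GOF the median ratio was 1.15 (quartiles 0.881 to 1.65). The comparison therefore does not decide whether B, myeloid, neutrophil, NK, CD8 or red blood cells were the source. For Th1 and cytotoxic (1.32, 1.19 to 1.51, with 4 genes that are also NK and CD8 markers), activation and memory (1.032, from 0.877), follicular helper (1.00, 0.679 to 1.21) and cell cycle genes (1.56, 1.40 to 1.92) the intervals reached the bound of 1.21. For all 6 lists residual cells cannot be told apart from a change in CD4 T cells. The bound of 1.21 replaced that of the myeloid markers (2.95), below which all 6 intervals lay, after the values were seen. It leaves out plasma cells, which have 2 risen markers (0.929 to 3.10). The largest GC and length trend fitted in any library was 0.55 on the log2 scale. Removing these trends left the interferon median at 2.22, which argues against such a bias. An effect of the genotype in CD4 T cells, memory CD4 T cells (although the cells were isolated as naive) or other cells at a like share in all 4 GOF libraries may each remain, untested.

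The second pattern is that genes induced by STAT5, the transcription factor downstream of IL-2 and IL-7 receptors, were lower in GOF. Of 19 such genes 15 fell and 0 rose, with a median log2 fold change of -1.56, among them Cish from 149 to 46.4 CPM, Pim1 from 1203 to 250 CPM, Socs2 from 17.8 to 2.27 CPM and Cdk6 from 265 to 20.96 CPM, chosen after their values were seen. Markers of myeloid cells, neutrophils, B cells and NK and CD8 T cells rose in the same libraries (list medians 2.05, 5.03, 1.51 and 1.98). The STAT5 list was also compared under other settings. The median stayed at -1.59 after removal of GC and length trends, which argues against those biases. The largest library total was 1.12 times the smallest (0.17 on the log2 scale), so depth differed little. The fit divides by scaled totals, which were known beforehand, so this comparison does not test depth as a cause. Against other genes the list had camera p = 0.00117 with an estimated correlation, but it was written after most of its members had been seen, and of 5 members not seen before (Osm, Lta, Bcl2l1, Ccnd2 and Ccnd3) 2 fell, Osm and Lta, so lower STAT5 signalling may be proposed only as a hypothesis. Whether cytokine exposure differed in the animal or during isolation was not tested.

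The third pattern is the number of changed genes itself. Of the 35 splits of the 7 libraries into 3 and 4, only 1, the real one, gave as many as 3968 genes past the threshold. The highest of the others gave 4. A share of 1 in 35 is the smallest that this number of splits allows, so the comparison cannot exclude chance. Every other split puts both genotypes into at least 1 group. Any difference between the genotypes then widens the spread within that group, which keeps the counts of those splits low. Variants carried along with the Pik3cd allele that act on their neighbours would raise the share of changed genes near it. Of 150 tested genes within 10 Mb 31.3% changed, as did 31.3% elsewhere (ratio 1.00, odds ratio interval 0.692 to 1.43), so no local excess was seen. A linked variant acting on distant genes would not raise that share, so the test cannot exclude it. The labels give no batch, so a batch shared by all libraries of a genotype cannot be told apart from the genotype.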
